A study of Mus musculus with 4 samples.

How the data were processed

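Total RNA from mouse 3D engineered muscle was profiled on 4 single-colour Agilent arrays of 1 slide, 1 array for each combination of stimulation (none, or 30 min of acute EPS) and time point (0 min or 5 h). Per the labels' protocols, RNA was extracted with acid guanidinium, phenol and chloroform, copied with oligo-dT primers carrying a T7 promoter and labelled with Cy3-CTP during in vitro transcription. The labelling protocol names leukocytes as the RNA source, whereas titles, tissue fields and the extraction protocol name engineered muscle; the arrays are treated as engineered muscle. The labels spell EPS as electrical plus stimulation, and it is read here as electrical pulse stimulation.

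Per the file headers, the deposited values are spot intensities from Agilent Feature Extraction 10.7.3.1, subtracted for background and detrended across the array, with a surrogate value where a spot was not above background. The deposited value table of the series holds the same intensities: all 44397 values on each of the 4 arrays equalled the processed signal of the same spot, so it is linear, uncentred and unscaled. Its column medians were 75.2 (no EPS, 0 min), 64.0 (no EPS, 5 h), 57.6 (EPS, 0 min) and 69.4 (EPS, 5 h). Flags of the scanner software, per the file headers, mark spots well above background, saturated spots and outliers; no spot was saturated. Each array held 43020 spots that are not controls, and 112 to 141 of its spots carried an outlier flag and were left out.

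The log2 of the processed signal minus the array's 75th percentile of that signal is called the level. Spots of 1 probe were averaged on the log2 scale, and a gene was represented by its brightest probe over the 4 arrays. Of 39429 probes, 26049 were matched by accession to the RefSeq gene table supplied with the data (assembly GRCm38.p6), which renamed 3357 of them, and 13380 kept the name in the array files. That table was used for names alone, since the array design gives positions on build mm9. The probes covered 31893 gene names, 6282 of them with several probes. Positions printed are those of the array files.

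Each comparison is a difference of levels between 2 arrays, and the comparison of EPS effects is a difference of 2 such differences. With 1 array per group there is no spread within a group, and no test between groups was run. An additive fit of EPS and time would leave 1 residual degree of freedom and was not made. No p-value was computed, and a size rule of 2-fold took the place of a test. The rule was applied to genes well above background on both arrays compared, or on all 4 for the difference of effects. For a gene well above background on 1 of the 2 arrays, a lower bound of the fold was taken against the higher of the dim probe's own level and the lowest level among probes well above background on that array. Technical error came from 399 probes printed 10 times on each array. It covers the spots of 1 labelled RNA sample and not the spread between tissues.

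The groups, comparisons, gene lists, rule for named genes and other settings were fixed before the data were examined. In each EPS comparison the named genes are Cck, Cckar and Cckbr, the 12 genes with the largest difference in each direction, up to 3 genes per direction with the largest lower bound, and up to 4 members of each list. The 12 had to reach 2-fold, have a mean level at or above the lower quartile of measured genes, have no measured probe going the other way and carry a gene name rather than a clone or accession number; 11 genes met these terms downward at 0 min. In the time comparisons the numbers were 5 per direction and up to 2 per list, and in the difference of EPS effects 5 per direction. The 25 lists covered immediate early genes, hypoxia and HIF targets, glycolytic enzymes, gut and neuropeptides, myokines and secreted factors, PGC-1 and oxidative metabolism, heat shock and chaperones, the unfolded protein and integrated stress response, and oxidative stress with metallothioneins. They also covered muscle proteolysis, sarcomere genes, myogenic regulators, NF-kB and inflammatory genes, interferon response, circadian clock, cell cycle, extracellular matrix, cholesterol synthesis and reference genes. The cell type lists were fibroblast, adipocyte, endothelial, leukocyte, neuron and Schwann cell, and bone and cartilage markers. Lists could share members: 10 of 38 hypoxia and HIF targets, 9 of 30 myokines and 4 of 29 NF-kB genes were also in another list. A list is described by the median difference of its measured members and by the percentile of that median among 10000 random lists of the same size drawn from genes matched on mean level in 20 bins. Percentiles at or under 2.5 or at or above 97.5 are called outside the random range; they describe these arrays and are not p-values.

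Alternatives were normexp background correction (offset 50) of the mean signal against the local background, quantile normalization, median centring, 3 other filters on dim genes, the mean of a gene's probes, size rules of 1.5-fold and 3-fold, and random lists without matching. Cyclic loess between arrays was added after the data had been seen. The procedure was tested on simulated data, with known folds placed on 50 genes per size and noise taken from the replicate spots. Of genes made 2-fold different, 50% were called at 0 min and 42% at 5 h. Of those made 3-fold or 4-fold different, 100% were called in both, and 0 of 18389 and 0 of 18342 unmodified genes were called. These outcomes follow largely from the setting: a 2-fold gene lies on the threshold, and the noise leaves out the spread between tissues. The simulation therefore checks the calculation and gives no rate of false calls between tissues. Of 200 random lists, 7.5% at 0 min and 5% at 5 h lay outside the random range. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.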

Results

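Mouse 3D engineered muscle, skeletal muscle tissue built in culture, was profiled with or without EPS, an electrical stimulus used to make cultured muscle contract. Unstimulated tissue was the negative control at each time point. The title of the series concerns hypoxia and the gene for cholecystokinin (Cck), a peptide hormone of gut and brain. The 4 groups were no EPS at 0 min, no EPS at 5 h, EPS at 0 min and EPS at 5 h, with 1 array each and no replicates, so the differences below describe these 4 arrays and carry no error between tissues. Genes well above background numbered 19164 for no EPS at 0 min, 19324 for no EPS at 5 h, 19420 for EPS at 0 min and 19171 for EPS at 5 h, and the 75th percentile of the signal was 1362.5, 1280.3, 1093 and 1491.9. Across 273 probes printed 10 times and measured on the arrays compared, the standard deviation between spots of a log2 difference had a median of 0.06 and a 95th percentile of 0.21 for EPS at 0 min, and 0.05 and 0.24 for EPS at 5 h.

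Cck was 1.26-fold lower with EPS at 0 min and 1.79-fold higher with EPS at 5 h. Its signal was among the brighter ones on the arrays: 14120 without EPS at 0 min, 11124 without EPS at 5 h, 8981.3 with EPS at 0 min and 23200 with EPS at 5 h, or levels of 3.37, 3.12, 3.04 and 3.96 on the log2 scale. Between 0 min and 5 h, Cck was 1.19-fold lower without EPS and 1.89-fold higher after EPS, and its EPS difference at 5 h exceeded that at 0 min by 1.17 on the log2 scale. It was measured by 1 probe, at chromosome 9, 121398943 to 121399002 on build mm9, and ranked 188 from the top among 18542 genes at 5 h. Cckar and Cckbr, which encode the receptors for cholecystokinin, were not well above background on any of the 4 arrays. The difference of 0.84 at 5 h is 3.55 times the 95th percentile of the spot error and lies below the 2-fold rule.

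**Figure D1:**
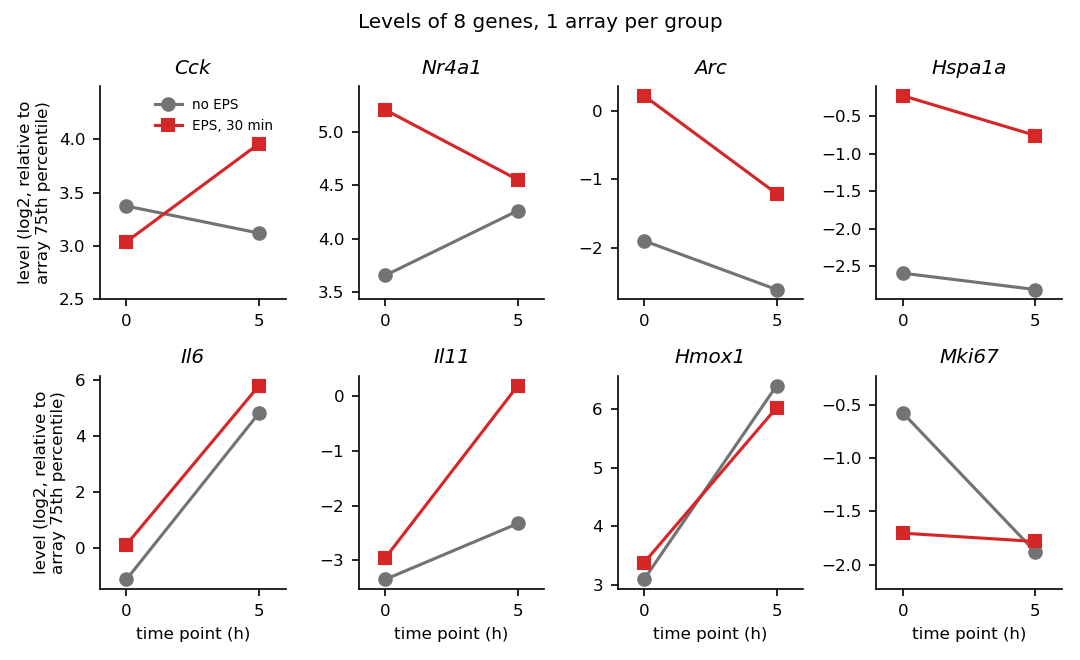
Level of 8 genes on each array (log2 of the signal relative to the array's 75th percentile, y axis) at 0 min and 5 h (x axis), without EPS (grey circles) and with EPS (red squares); each point is 1 array and lines join the arrays of 1 arm. Cck stood at 3.96 with EPS at 5 h and between 3.04 and 3.37 on the other arrays, Hspa1a was higher with EPS at both times, and Mki67 was highest without EPS at 0 min.

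Directly after stimulation, activity-induced genes and the heat shock genes Hspa1a and Dnajb1 were higher with EPS than in unstimulated tissue. The heat shock list was higher and the cell cycle list lower, but both stood apart in the same direction in unstimulated tissue at 5 h against 0 min (medians 0.24 and -0.25), so these list differences are not unique to the EPS comparison. Hspa1a, the inducible heat shock protein of the Hsp70 family, was 5.14-fold higher, and its co-chaperone Dnajb1 3.48-fold higher. Arc, a classic activity-induced gene, was 4.35-fold higher, and the orphan nuclear receptors Nr4a2 and Nr4a1 were 4.04-fold and 2.93-fold higher. Nr4a2 had its lowest level on the unstimulated 0 min array (-0.74), against 1.28 with EPS at 0 min and 2.17 without EPS at 5 h. Its difference is therefore not unique to the EPS comparison either. Mki67, the Ki-67 proliferation antigen, was 2.19-fold lower, and the nuclear long non-coding RNA Malat1 3.16-fold lower. In all, 102 of 18589 genes were at least 2-fold higher with EPS and 147 at least 2-fold lower.

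Other genes higher at 0 min were Dusp2, a phosphatase of MAP kinases (2.79-fold), Cish, a feedback inhibitor of cytokine signalling (2.56-fold), and the pseudogene Usp-ps (2.97-fold). Ggcx, the vitamin K-dependent gamma-glutamyl carboxylase, was 6.30-fold higher, Ppp5c, a serine/threonine phosphatase, 6.28-fold higher, and Nelfe, a subunit of the negative elongation factor, 4.52-fold higher. These 3 were low on the unstimulated 0 min array alone: Ggcx had a level of -4.22 there and between -1.88 and -1.56 on the other arrays, and Nelfe -0.98 against 1.20 to 1.29. Downward, Hdc (histidine decarboxylase) was 2.95-fold lower, Igfbp2 (an insulin-like growth factor binding protein) 2.77-fold, the linker histone H1f5 2.74-fold, Eid3 2.71-fold, Ppnr 2.64-fold and the semaphorin receptor Plxna1 2.22-fold. Usp44 was 2.25-fold lower, Rsad1 2.22-fold and Pimreg 2.06-fold. Hdc, Plxna1, Usp44, Rsad1 and Mki67 were high on the unstimulated 0 min array alone, as with Hdc at -1.78 there and between -3.51 and -2.88 on the others. Among genes seen above background in 1 of the 2 groups, the neurofilament gene Nefl was at least 26.6-fold lower with EPS, Fscb at least 8.26-fold and Klk8 at least 8.13-fold. Klra22 was at least 8.31-fold higher, Olfr1497 at least 8.22-fold and Gsg1l at least 8.11-fold. Bounds over 2-fold were found for 86 genes upward and 94 downward, and a bound makes no allowance for spot error. Nefl had its highest level on the unstimulated 0 min array (-1.48, against -7.90 with EPS). It was also lower at 5 h in unstimulated tissue, a comparison with the same control array.

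Immediate early genes formed the most displaced list at 0 min: 10 of 35 measured members were at least 2-fold higher, none 2-fold lower, and 34 lay above 0, with a median log2 difference of 0.59, above all 10000 matched random lists. Ccn1, a matricellular gene of this list, was 2.53-fold higher. Hypoxia and HIF targets had a median of 0.21, also above all random lists, with 26 of 37 members above 0; Angptl4 differed by 0.64, Bnip3 by 0.50 and Ankrd37 by -0.93. Myokines and secreted factors had a median of 0.25 and NF-kB and inflammatory genes one of 0.28, both above all random lists. Both were also higher in unstimulated tissue at 5 h against 0 min (0.23 and 0.54), a comparison with the same control array. These lists overlap, with Il6, Cxcl1, Cxcl5 and Ccl2 in both, so they are not separate results for those genes. Il6 was 2.37-fold higher, Ptgs2, the inducible cyclooxygenase, 2.36-fold, Cxcl1 1.93-fold and Ccl2 1.72-fold. Heat shock and chaperone genes had a median of 0.23 (percentile 99.99, 2 of 19 at least 2-fold higher) and the unfolded protein and integrated stress response list 0.16 (percentile 99.79, 0 of 27 at 2-fold), with Slc7a11, the cystine transporter, at 0.81 and Trib3 at 0.58.

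Cell cycle genes had a median of -0.39 at 0 min, below all random lists, with 18 of 22 members below 0 and 1 (Mki67) at 2-fold; Top2a differed by -0.87, Plk1 by -0.84 and Bub1 by -0.83. Neuron and Schwann cell markers had a median of -0.25 (percentile 0.59), with 7 of 8 members below 0 and Tubb3 at -0.35. In unstimulated tissue at 5 h against 0 min, with the same control array, this list stood at -0.32 (percentile 3.84, inside the random range). Medians inside the random range were 0.17 for glycolytic enzymes, -0.02 for gut and neuropeptides (7 of 27 measured), 0.03 for PGC-1 and oxidative metabolism, 0.10 for oxidative stress, 0.01 for muscle proteolysis, 0.12 for sarcomere genes, -0.02 for myogenic regulators and -0.05 for interferon response. They were 0.02 for circadian clock, 0.02 for extracellular matrix, -0.01 for cholesterol synthesis and 0.12 for reference genes. Of the other cell types, fibroblast markers had a median of 0.10, adipocyte markers 0.22, endothelial markers -0.13, leukocyte markers 0.02 and bone and cartilage markers -0.11. Cd68, a macrophage marker, was 2.52-fold lower, at a dim level of -3.69 without EPS. Under normexp background correction 42 genes were higher and 29 lower, all of these 71 among the 249 of the main setting; Usp44, Rsad1, Pimreg and Cd68 then stood at -0.87, -0.78, -0.66 and -0.58, under 2-fold.

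**Figure D2:**
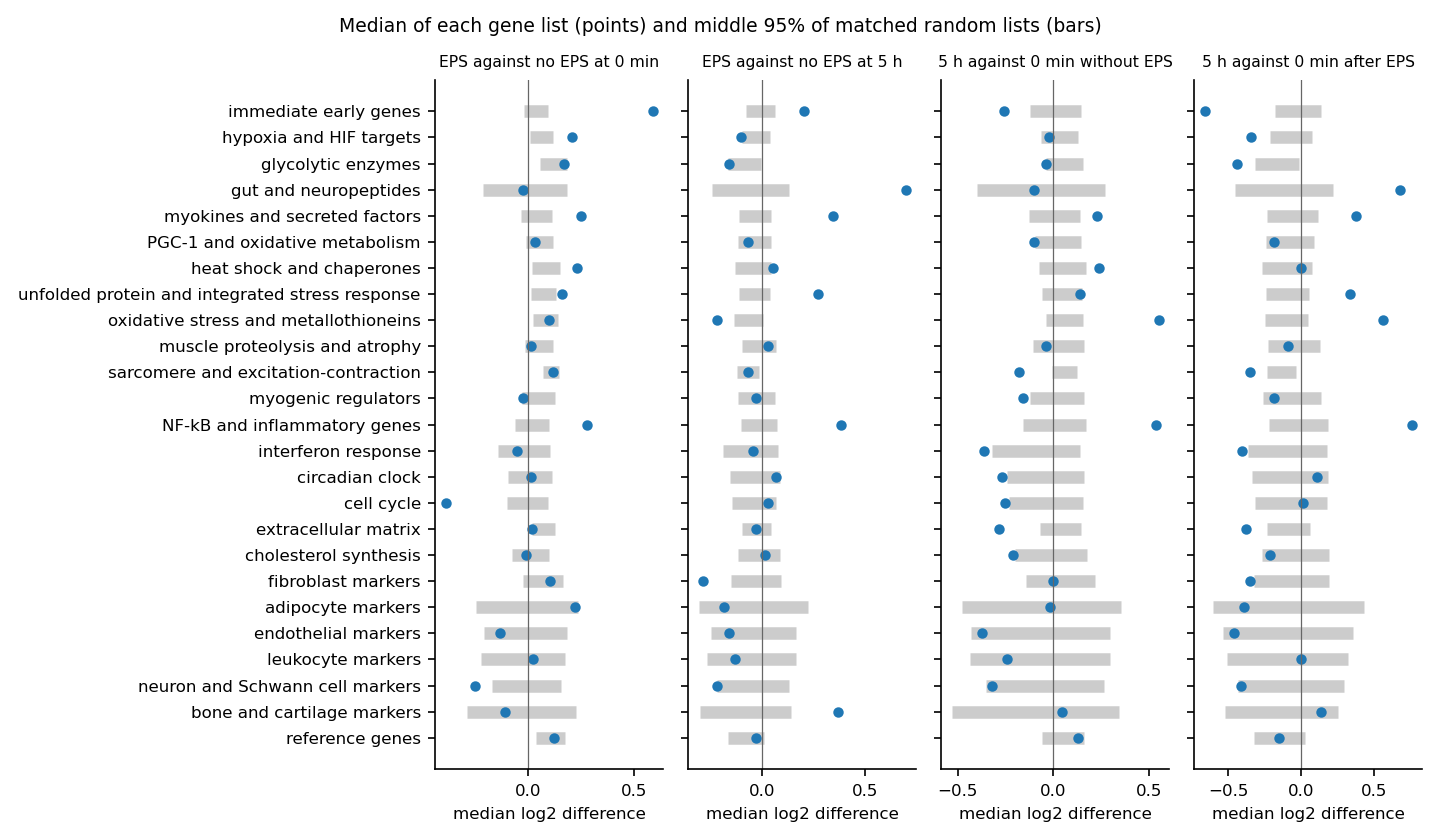
Median log2 difference of each of the 25 gene lists (points, x axis) in the 2 EPS and the 2 time comparisons (panels); grey bars span the middle 95% of the medians of 10000 matched random lists. Immediate early genes stood at 0.59 with EPS at 0 min and cell cycle genes at -0.39, and gut and neuropeptides stood at 0.70 with EPS at 5 h.

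At 5 h several cytokine and chemokine genes were among those higher with EPS than in unstimulated tissue. Serpinb2, plasminogen activator inhibitor 2, was 20.9-fold higher, Il11 and Lif, cytokines of the interleukin-6 family, 5.74-fold and 5.52-fold, and the neutrophil chemokines Cxcl5 and Cxcl1 3.89-fold and 3.498-fold. Hspa1a was 4.14-fold higher, as it had been 5.14-fold higher at 0 min. The vasoactive peptides apelin (Apln) and adrenomedullin (Adm) were lower, with log2 differences of -1.32 and -1.09. In all, 128 of 18542 genes were at least 2-fold higher with EPS and 97 at least 2-fold lower.

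Further upward differences at 5 h were those of Rgs16, a regulator of G protein signalling (6.40-fold), Il1rl1, the interleukin-33 receptor (5.50-fold), Olr1, a receptor for oxidized low-density lipoprotein (5.08-fold), S100a8, a calcium-binding protein of neutrophils (4.60-fold), Lce1g (4.05-fold) and Inhba, which encodes the subunit of activin A (3.40-fold). Downward, Syt10, a synaptotagmin, was 2.84-fold lower, the prostaglandin F receptor Ptgfr 2.80-fold and the noradrenaline transporter Slc6a2 2.54-fold. Akr1c14 was 2.27-fold lower, Gbp6 2.23-fold, Ssh2 2.16-fold, the leptin receptor Lepr 2.16-fold, Inmt 2.14-fold, the glutamate transporter Slc1a3 2.12-fold and the chemokine Cxcl12 2.07-fold. Among genes above background in 1 of the 2 groups, Cacna1e was at least 8.96-fold higher, Cd2 at least 8.66-fold and Rdh19 at least 8.36-fold, and Prss43 was at least 13.0-fold lower, Crnn at least 12.5-fold and Htr3b at least 11.3-fold. Bounds over 2-fold were found for 80 genes upward and 113 downward, again with no allowance for spot error.

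Gut and neuropeptide genes, the list that holds Cck, had a median of 0.70 at 5 h, above all random lists, with 8 of 9 measured members above 0. Penk, the enkephalin precursor, was 3.20-fold higher, the secretogranin gene Scg2 2.52-fold and the neuropeptide precursor Vgf 1.89-fold; 15 of the 27 listed genes were not well above background on any array. Without the background filter the median of gut and neuropeptides with EPS at 5 h was -0.04 (percentile 89.6, inside the random range). Myokines and secreted factors had a median of 0.34, with 7 of 28 at least 2-fold higher and 1 lower. NF-kB and inflammatory genes had one of 0.38, with 6 of 22 higher, and both medians lay above all random lists. Il6, Cxcl1, Cxcl5 and Ccl2 are members of both lists. The collagenase Mmp13 was 3.28-fold and Ccl2 3.12-fold higher. In the unfolded protein and integrated stress response list, 4 of 27 genes were at least 2-fold higher, all of the endoplasmic reticulum: Creld2 (3.08-fold), Manf (2.25-fold), Sdf2l1 (2.24-fold) and the disulfide isomerase Pdia4 (2.04-fold), with a median of 0.27 above all random lists. Immediate early genes had a median of 0.21, above all random lists, with Arc (2.64-fold) and Dusp5 (2.24-fold) at 2-fold. Heat shock and chaperone genes had a median of 0.05 (percentile 98.41, but 97.38 with the mean of probes and 93.43 among random lists without matching), with 1 of 19, Hspa1a, at 2-fold.

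Hypoxia and HIF targets had a median of -0.10 at 5 h (percentile 1.67), with 25 of 37 members below 0 and Adm at 2-fold; Ankrd37 differed by -0.67, while Angptl4 differed by 0.69. Oxidative stress and metallothionein genes had a median of -0.22, below all random lists, with 22 of 24 below 0 and none at 2-fold; the glutathione transferase Gsta4 differed by -0.59 and the ferritin gene Ftl1 by -0.48. Fibroblast markers had a median of -0.29 (percentile 0.01), with all 10 measured members below 0, none at 2-fold and the receptor Pdgfrb at -0.87. Whether this concerns the share of fibroblasts in the tissue was not tested. Neuron and Schwann cell markers had a median of -0.22 at the edge of the random range (percentile 2.35, and 3.74, 2.505 and 2.82 under the filters on at least 1 array, on all 4 arrays and without a filter) and bone and cartilage markers one of 0.37 (percentile 99.94), with alkaline phosphatase (Alpl) 2.02-fold higher and osteopontin (Spp1) 1.63-fold. Medians inside the random range were -0.16 for glycolytic enzymes, -0.07 for PGC-1 and oxidative metabolism, 0.03 for muscle proteolysis, -0.07 for sarcomere genes, -0.03 for myogenic regulators, -0.04 for interferon response, 0.07 for circadian clock and 0.03 for cell cycle. They were -0.03 for extracellular matrix (tenascin C, Tnc, was 2.01-fold higher), 0.01 for cholesterol synthesis, -0.03 for reference genes, -0.19 for adipocyte, -0.16 for endothelial and -0.13 for leukocyte markers. Under normexp background correction 43 genes were higher and 31 lower, all among the 225 of the main setting, and Akr1c14, Gbp6, Ssh2 and Slc1a3 stood at -0.93, -0.94, -0.88 and -0.97, Dusp5 at 0.57, Scg2 at 0.76, Pdia4 at 0.98, Mmp13 at 0.94, Tnc at 0.78 and Alpl at 0.49, under 2-fold. With the mean of its probes in place of the brightest, Cxcl12 differed by -0.92, and the percentile of the hypoxia list was 3.52 under normexp and 5.22 among random lists without matching.

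The EPS differences at both times shared few genes. Of 18107 genes well above background on all 4 arrays, 9 were at least 2-fold higher with EPS at both times, against 0.45 for independent sets of 84 and 97 genes; they include Arc, Hspa1a, the inducible cyclooxygenase Ptgs2, Rgs16 and 3 members of the Usp17-like deubiquitinase family and its pseudogene (Usp17la, Usp17lb and Usp-ps). A further 12 were lower at both times, against 0.57 for independent sets of 121 and 85; the named ones are Acsm1, the retinoic acid binding protein gene Crabp1, Zbed3 and Zfp395. These overlap genes were named after their values had been seen. The figures for independent sets, here and in the time comparisons, take genes as unrelated and are not matched on level. With 3 of the 9 from 1 family, the excess over 0.45 is a description and not a test. Higher at 0 min and lower at 5 h were 2 genes, H2bfm among them, and Ly6f alone went the other way. Across genes, which are not independent replicates, the EPS differences had Pearson's r = 0.28 and Spearman's rho = 0.28, and the 2 comparisons share no array.

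**Figure D3:**
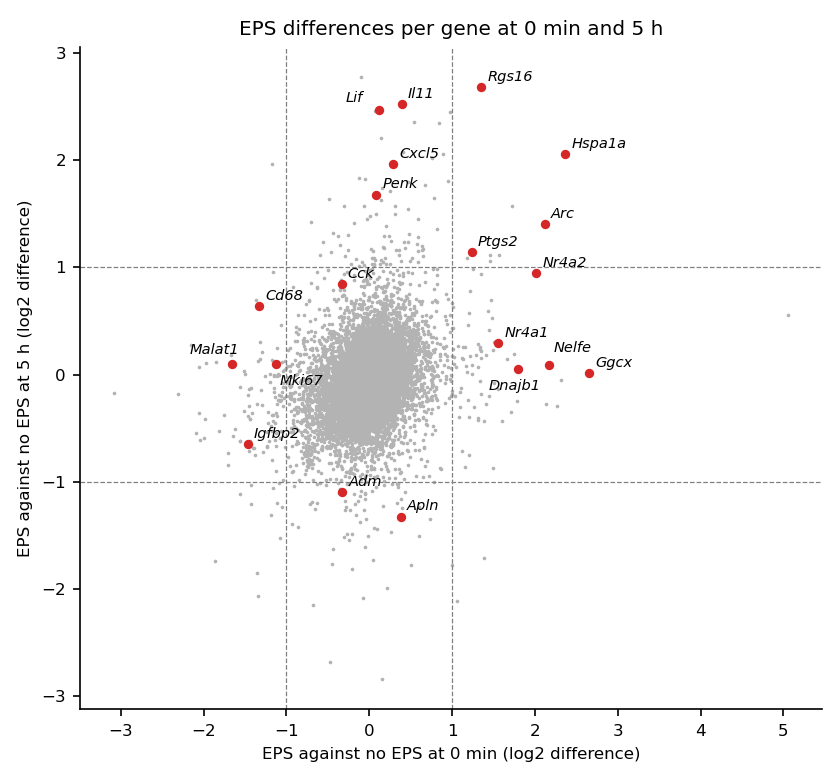
Log2 difference between EPS and no EPS at 0 min (x axis) and at 5 h (y axis) for the 18107 genes well above background on all 4 arrays (grey points); red points are named genes and dashed lines mark 2-fold. Hspa1a, Arc, Rgs16 and Ptgs2 lie beyond 2-fold at both times, Ggcx at 0 min alone, and Il11, Lif and Cxcl5 at 5 h alone.

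The difference of the EPS effects, 5 h minus 0 min, was at least 2-fold upward for 181 of 18107 genes and downward for 180. Among genes with a mean level at or above the lower quartile, those upward were Il1rl1 with a difference of 2.39 on the log2 scale, Il11 (2.13), S100a8 (2.06), Malat1 (1.75) and the organic anion transporter gene Slco4a1 (1.71). Downward stood Ggcx (-2.64), Ppp5c (-2.63), Nelfe (-2.08), the transcription factor gene Cebpd (-1.78) and D11Ertd726e (-1.75). For Ggcx, Ppp5c, Nelfe and D11Ertd726e the unstimulated 0 min array stood alone, so their values here rest on that array. Malat1 was low on the EPS 0 min array alone, with a level of 0.03 against 1.07 to 1.69 on the others. Bone and cartilage markers had a median difference of 0.49, cell cycle genes one of 0.48 and gut and neuropeptides one of 0.45. The cell cycle median with EPS was -0.39 at 0 min and 0.03 at 5 h, so this difference too rests on the 0 min arrays. Immediate early genes stood at -0.44, adipocyte markers at -0.41 (4 of 4 below 0), glycolytic enzymes at -0.38, fibroblast markers at -0.38, oxidative stress genes at -0.27 and hypoxia and HIF targets at -0.25. This difference has no test, and under normexp 34 genes were upward and 75 downward, 105 of these 109 among the 361 of the main setting.

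Time in culture separated the arrays further than EPS did. In unstimulated tissue, the cytokine Il6 was 61.9-fold higher at 5 h than at 0 min, the pentraxin Ptx3 18.4-fold, the neuropeptide Y receptor Npy1r 16.1-fold, Cxcl5 13.8-fold and the protease inhibitor Slpi 10.4-fold. Gprin3 was 10.6-fold lower, Ranbp3l 8.18-fold, Nefl 8.06-fold, the immediate early transcription factor Egr1 7.39-fold and Pid1 6.31-fold. In all, 322 of 18486 genes were at least 2-fold higher and 547 at least 2-fold lower, and the standard deviation of the log2 difference across genes was 0.49, against 0.30 for each of the EPS comparisons.

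Oxidative stress genes had a median of 0.55 over time without EPS, above all random lists, with 11 of 24 at least 2-fold higher; haem oxygenase 1 (Hmox1) was 9.85-fold and the quinone reductase Nqo1 8.13-fold higher. Slc7a11 was 19.9-fold higher. NF-kB and inflammatory genes had a median of 0.54 and myokines one of 0.23. Immediate early genes had a median of -0.26, with 7 of 34 at least 2-fold lower and 2 higher, one of them Nr4a2 (7.47-fold). Heat shock and chaperone genes stood at 0.24 (percentile 99.83, with 17 of 19 above 0 and none at 2-fold). Extracellular matrix genes stood at -0.28 (Col1a1 at -0.71), sarcomere genes at -0.18 (Myh4 at -0.72) and cell cycle genes at -0.25 (Ccna2 at -1.53, Mki67 at -1.31). Ppargc1a, the coactivator PGC-1 alpha, was 3.51-fold lower, the clock output gene Dbp 3.42-fold, Cd68 3.58-fold and the fibroblast and pericyte receptor gene Pdgfrb 3.41-fold. Under normexp 185 genes were higher and 226 lower, and Pax7, Oasl2, Per3, Cd68, Coro1a and Stc2 no longer reached 2-fold.

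After EPS the same contrast of 5 h with 0 min gave Il6 51.5-fold higher, Cxcl5 44.2-fold, the lubricin gene Prg4 18.1-fold, Slpi 15.2-fold and Fam110c 14.9-fold. Egr1 was 11.1-fold lower, Slc6a2 9.65-fold, Fos 9.46-fold, Cxcl12 8.83-fold and Egr2 8.69-fold. In all, 442 of 18468 genes were at least 2-fold higher and 673 at least 2-fold lower. Another probe of Prg4 differed by 0.11 and another of Fam110c by 1.82, so both values rest on the choice of the brightest probe. Fos is printed 10 times on the array, and its difference of -3.24 had a standard deviation of 0.07 between spots.

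Immediate early genes had a median of -0.66 over time after EPS, below all random lists, with 13 of 34 at least 2-fold lower and 2 higher. Oxidative stress genes stood at 0.56 (Nqo1 8.16-fold and Hmox1 6.24-fold higher), NF-kB and inflammatory genes at 0.76, gut and neuropeptides at 0.68 (Scg2 4.74-fold and Npy 3.45-fold higher), and the unfolded protein and integrated stress response at 0.33. The gut and neuropeptide median rests on 10 of 27 listed genes and turned to -0.09 without the background filter. Glycolytic enzymes stood at -0.44, hypoxia and HIF targets at -0.35 (Pdk1 at -1.10; percentile 0.01, and 2.96 under quantile normalization) and sarcomere genes at -0.35. Extracellular matrix genes stood at -0.38, below all random lists, and fibroblast markers at -0.35 (percentile 1.3, and 4.27 among random lists without matching), with 9 of 10 below 0 and Pdgfrb 5.38-fold lower. Of the genes well above background on all 4 arrays, 193 were at least 2-fold higher over time in both arms, against 6.998 for independent sets of 301 and 421, and 294 were lower in both, against 17.9 for sets of 500 and 647; the arms share no array, and r across genes was 0.78. Quantile normalization gave 529 genes higher and 517 lower after EPS and cyclic loess, chosen after the data had been seen, 550 and 526, while normexp gave 256 and 343; Scg2 and Npy then stood at 0.94 and 0.49.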

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

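The tests of unstimulated tissue over time and of the hypoxia list at 5 h were chosen after their values had been seen, as was cyclic loess; the thresholds of the others were written before those tests were run. Effects of EPS of opposite sign at 0 min and 5 h drew attention to 4 results, and with 1 array per group no such difference was tested. Cck differed by -0.33 at 0 min and 0.84 at 5 h, Apln by 0.38 and -1.32, Cd68 by -1.33 and 0.64, and the median of the hypoxia and HIF target list by 0.21 and -0.10.

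Cck was 1.79-fold higher with EPS at 5 h, on 1 probe. Scaling and background correction do not account for it, since the lowest difference under quantile normalization, median centring, normexp and cyclic loess was 0.85. The 37 HIF targets were not raised as a list at 5 h, with a median of -0.10, and between -0.09 and -0.05 under the same settings. That test was chosen after its value had been seen and rests on 1 array per group, so it cannot exclude a hypoxia response still raised at 5 h. A delayed effect of an earlier response, with the list at 0.21 at 0 min, also stays open. Spread between tissues stays open too: 0.36% of 1104 genes of similar brightness were as far apart as Cck, under the 1% set beforehand as speaking against it, but that bound was wrong because 1 array per group measures no spread of Cck between tissues. An effect of EPS on Cck is therefore a hypothesis that could be tested with replicate tissues.

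Cell cycle genes were lower with EPS at 0 min, with a median of -0.39. Scaling between arrays does not account for this, since the median stayed at or below -0.28 under the 4 settings. The same list was lower at 5 h than at 0 min in unstimulated tissue, with a median of -0.25 (percentile 1.73), and it stood at 0.03 with EPS at 5 h. An effect of EPS and a difference of the unstimulated 0 min tissue therefore cannot be told apart, because that array is the control of both comparisons. The same limit, seen afterwards, holds at 0 min for the heat shock list (0.23 with EPS and 0.24 over time without EPS), NF-kB genes (0.28 and 0.54) and myokines (0.25 and 0.23). Neuron and Schwann cell markers (-0.25 and -0.32) and the unfolded protein and integrated stress response list (0.16 and 0.14) also kept their sign. Their medians over time without EPS lay inside the random range (percentiles 3.84 and 95.93).

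Of the 249 genes at least 2-fold apart at 0 min, 60 had the EPS array within 1.5-fold of both 5 h arrays, so that the unstimulated array stood alone, as for Ggcx, Ppp5c, Nelfe, Hdc, Plxna1, Usp44, Rsad1, Mki67 and Cd68; in 54 others the EPS array stood alone. Spots of the 60 genes lay closer together than random spots, at percentile 3.34 of the median nearest distance (143 against 180 in the position units of the array files). A local effect on that array could give this. The spots of the 54 others lay at percentile 71.4. Defects of single spots cannot be told apart from differences of the tissue, since 3 of 6 second probes (50%, exact 95% interval 11.8% to 88.2%) differed by 1.5-fold or more the same way. A difference of the unstimulated tissue itself was not tested.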

How the results depend on the processing

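Cyclic loess was chosen after the data had been seen; the other settings were set before the data were examined. Counts below are genes higher then lower with EPS at 0 min, with EPS at 5 h, over time without EPS, over time after EPS and in the difference of EPS effects, then genes higher at both times and lower at both times. Normexp gave 42, 29, 43, 31, 185, 226, 256, 343, 34, 75, 4 and 1; its offset of 50 pulls dim signals together by construction, and how far this accounts for its counts was not tested. Genes above background on at least 1 array gave 497, 527, 477, 550, 746, 1024, 858, 1316, 849, 988, 32 and 61, and no background filter 1074, 1172, 1085, 1445, 1234, 1877, 1396, 2541, 1861, 2117, 109 and 243, by construction on more and dimmer genes. A 1.5-fold rule gave 374, 621, 382, 548, 1220, 1734, 1459, 2307, 610, 725, 51 and 126, and a 3-fold rule 24, 33, 37, 23, 108, 135, 124, 157, 37, 44, 1 and 1. Every one of these counts stayed within 1.5 times the main value under quantile normalization, median centring, cyclic loess, the mean of probes and the filter on all 4 arrays, and Cck kept its signs under all settings run. The share of higher genes was 59.2% under normexp against 41.0% with EPS at 0 min, 31.2% against 50.1% in the difference of effects, and 50.6% (quantile) and 51.1% (cyclic loess) against 39.6% over time after EPS. The median of the gut and neuropeptide list turned to -0.0375 with EPS at 5 h and -0.0922 over time after EPS without the background filter, which adds its undetected members. The values deposited for the series equal the scanner signals, so that alternative was not run separately, and a slide block was not run because there is 1 slide. The labels carry no replicate numbers to pair arrays by; pairing EPS with no EPS within each time point would give 2 pairs and was not done. Signal over background limits dim genes: the lowest signal well above background was 14.8 to 20.3, and about 61% of probes passed.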

Other observations

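Some genes outside the main groups also differed over time. Slc6a2, the noradrenaline transporter gene, was 9.65-fold lower at 5 h after EPS. Nefl was 8.06-fold lower at 5 h without EPS (levels -1.48 and -4.49), while after EPS it was not above background at 0 min (level -7.90) and stood at -4.78 at 5 h. Endothelial markers had medians of -0.37 without EPS and -0.46 after EPS (percentiles 4.47 and 5.17, inside the random range), with Ramp2 1.84-fold and 2.01-fold lower; after EPS it differed by less than 2-fold under normexp (-0.94), quantile normalization (-0.996) and median centring (-0.94). Interferon response genes had medians of -0.36 and -0.40 (percentiles 1.20 and 1.26, calls that some filters and, without EPS, normexp moved inside the random range), with Ifit3 at -1.64 and -1.14; under normexp Ifit3 stood at -0.86 after EPS. Circadian clock genes had a median of -0.27 without EPS (percentile 1.38, and 2.6 under the filter on all 4 arrays) and 0.11 after EPS (percentile 91.7), with Dbp at -1.77 and -2.14. Cholesterol synthesis genes had medians of -0.21 in both arms (percentiles 1.91 and 7.2, the first 2.54 among random lists without matching), with Mvk at -0.62 and -0.92. Cd14, a lipopolysaccharide co-receptor of macrophages and other cells, was 3.98-fold higher at 5 h after EPS, and Coro1a, a leukocyte gene, 2.89-fold lower.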
